A study of Mus musculus with 10 samples.

How the data were processed

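ATAC-seq was measured in 10 libraries of innate lymphoid cells sorted from the small intestinal lamina propria of C57BL/6 mice with Id2-driven, tamoxifen-inducible Cre and a red fluorescent reporter, per the labels' protocols. The groups were Control (n = 3), RORgt-KO (n = 2), RORgt-Tbet-KO (n = 2) and RORgt-RORa-KO (n = 3), and each library was a biological replicate from 1 mouse or from 2 or 3 pooled mice. Tissue was digested with collagenase, cells were enriched magnetically and sorted, and nuclei were tagged with Tn5 in digitonin, per the labels' protocols. The surface markers of the sort, the batches, the sex of the mice and the floxed exons are not given in the sources used here.

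The authors trimmed reads with Trim Galore 0.62, aligned them with Bowtie2 2.3.5.1, filtered them with SAMtools and called peaks with MACS2 on GRCm38, per the submitters' processing notes. The values are log2 scaled read counts per peak, as deposited by the authors in 1 table of 36262 peaks; the scaling factor's origin is not given in the sources used here. All analyses below were computed from this table. Raised to the power of 2, the values of all non-empty peaks in each library were whole multiples of 1 step within a tolerance of 0.01. Empty peaks held 0.9 of that step. Dividing by the step recovered the reads: 3382309, 3361972 and 2519644 in Control, 3389482 and 2631420 in RORgt-KO, 4581343 and 5048636 in RORgt-Tbet-KO, and 2826415, 2272276 and 4734879 in RORgt-RORa-KO. The 11 peaks on Y were left out, which left 36251 peaks with a median length of 480 bp.

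Each peak was given the nearest protein-coding gene within 50 kb of the gene body, which named 32568 peaks and 13132 genes. The gene table used here has no strand, exons or sequence. Distance to the gene body therefore replaced distance to the transcription start, and places were recorded as within 1 kb of a gene end, inside a gene or between genes. A correction for GC content and an association with sequence motifs were planned and not run, because no genome sequence was used here.

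Peaks were tested with limma 3.58.1 in R 4.3.3 on the deposited values, with a mean-variance trend and all 4 groups in 1 fit (6 residual and 22.5 prior degrees of freedom). The 6 contrasts and a moderated F test were adjusted over all peaks by the Benjamini-Hochberg method at 0.05; every p of a peak in the report comes from limma, and SE is its moderated standard error. The log2 values as deposited were tested, and limma voom on the recovered reads was added as an alternative after the data were seen. A test on simulated data changed 200 peaks: 21% to 42% of 2-fold and 70% to 87% of 4-fold changes were recovered over the 6 contrasts, with at most 13 false calls. The median SE of a contrast was 0.27 to 0.33 on the log2 scale. Places of called peaks were compared with the other peaks by Fisher's exact test.

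Before the values were seen, 17 gene lists with 224 genes were fixed; 184 had a peak. They covered type 3, LTi-like ILC3, type 1 and NCR, type 2, ILC transcription factor, pan-ILC surface, clock and REV-ERB/ROR response, MHC class II, AHR pathway, homing and residency, and immediate early genes, and markers of T, B, myeloid, epithelial, stromal and endothelial cells, with housekeeping genes. Each list was tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a contrast, and its genes were also adjusted over the list alone. Of 102 list tests, 23 passed at the preset correlation and 0 with an estimated correlation.

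The rule for named peaks was fixed in advance: every peak in the targeted genes, the 5 peaks with the largest increases and the 5 with the largest decreases past the threshold (libraries of the groups not overlapping, 1 peak per gene, predicted genes left out), and, from each list, the best peak of the 3 genes with the smallest p past the threshold. Some peaks that this rule names are not reported here. Genes given only as members of a list come from the list's own calls. A gene counts as changed if any of its peaks passed, so genes with many peaks are counted more often. Over all peaks, 12.3%, 22.6% and 31.2% changed in RORgt-KO, RORgt-Tbet-KO and RORgt-RORa-KO against Control. Fold changes of contrasts were correlated across peaks and set against 100 simulated sets with unchanged groups, to show what shared controls give. Figures were drawn with matplotlib 3.10.9. Alternatives covered other scalings, the trend, filters, pseudocounts, library weights, a replicate block, list peaks limited to the gene body and 5 kb around it, the fry test of lists and leaving out each library; others were added after the data were seen.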

Results

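Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in innate lymphoid cells (ILCs) sorted from the small intestinal lamina propria of C57BL/6 mice. ILCs are tissue lymphocytes without rearranged antigen receptors. The mice carried a red fluorescent reporter, a tamoxifen-inducible Cre recombinase driven from Id2, and loxP-flanked alleles for the deletions that name the groups. RORgt is the factor that defines group 3 ILCs, Tbx21 encodes T-bet, the factor of type 1 lymphocytes, and Rora encodes the related nuclear receptor RORa. The 10 libraries comprised Control (n = 3; Cre and reporter without floxed alleles), RORgt-KO (n = 2), RORgt-Tbet-KO (n = 2) and RORgt-RORa-KO (n = 3). Each library was a biological replicate from 1 mouse or from 2 or 3 pooled mice. Reads in peaks ranged from 2272276 in RORgt-RORa-KO replicate 2 to 5048636 in RORgt-Tbet-KO replicate 2, and the median peak held 37 to 73 reads per library. Accessibility is given as the authors' log2 scaled read count per peak, positions are on GRCm38, and a peak is named after the nearest protein-coding gene within 50 kb.

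Across 36251 peaks, libraries of one group correlated at r = 0.908 to 0.967, while Control and RORgt-RORa-KO libraries correlated at 0.741 to 0.819. Libraries of different knockout groups lay partly within the range of single groups, RORgt-KO with RORgt-Tbet-KO at 0.916 to 0.936, RORgt-KO with RORgt-RORa-KO at 0.883 to 0.940 and RORgt-Tbet-KO with RORgt-RORa-KO at 0.857 to 0.922. The first principal component (46.6% of the variance) placed the controls at -133, -119 and -78.3, with replicate 3 the nearest to the knockouts, and the knockouts between 16.8 and 81.9. The second component (15.8%) separated RORgt-Tbet-KO, at 74.3 and 69.9, from RORgt-RORa-KO, at -41.8, -81.2 and -3.64. In limma's moderated F test, 11142 peaks (30.7%) differed among the 4 groups.

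**Figure D1:**
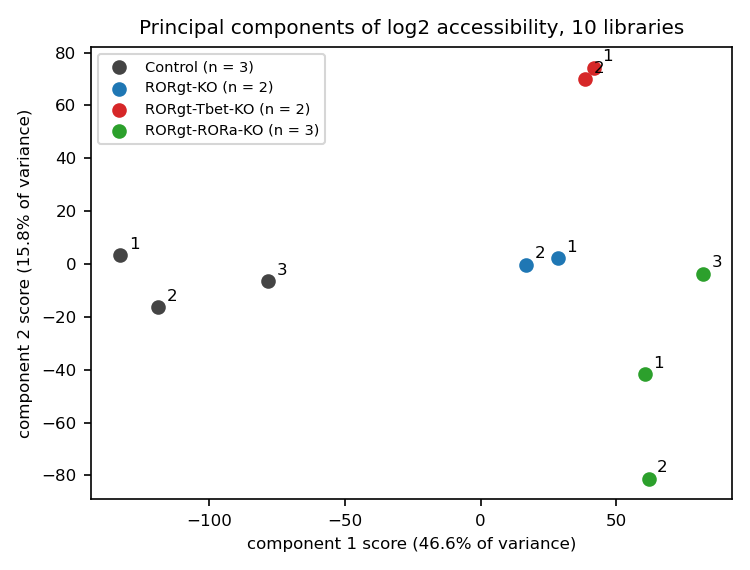
Scores of the 10 libraries on the first component (horizontal, 46.6% of the variance) and the second (vertical, 15.8%), each point a library with its replicate number, coloured by group. The controls lie at -78.3 or below on the first component and the 2 RORgt-Tbet-KO libraries lie highest on the second, at 69.9 and 74.3.

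The targeted genes Rora and Tbx21 were examined first. None of the 14 peaks in Rora (chromosome 9, 68653404 to 69388246) passed the test as lower in RORgt-RORa-KO; 3 rose, the one at 69034174 by 1.11 (SE 0.21, limma adjusted p = 0.000173). Of 2 peaks in Tbx21 (chromosome 11, 97098007 to 97115331), the one at 97112532 rose in RORgt-Tbet-KO by 1.76 (SE 0.29, adjusted p = 6.07e-05). Which exons were flanked by loxP is not given in the sources used here, and a peak outside the deleted part does not test the deletion.

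RORgt-KO was compared with the controls to find the accessible regions that depend on RORgt. Peaks of the interleukin-17 and interleukin-22 genes, the signature cytokines of group 3 ILCs, closed. A peak 44632 bp from Il17a (chromosome 1, 20685830 to 20686273) fell by 3.01 on the log2 scale (SE 0.45, 8.04-fold, adjusted p = 4.05e-05; 3.60 ± 0.20, SD, n = 2, against 6.61 ± 0.09, n = 3). One at the end of Il17f fell by 1.81 (SE 0.27), and one 13890 bp from Il22 fell by 1.95 (SE 0.37). In the opposite direction, peaks rose at Il12rb2, the interleukin-12 receptor chain (chromosome 6, 67347988 to 67348479; 2.34, SE 0.28, 5.07-fold, adjusted p = 1.69e-06), at the cytotoxic granule gene Nkg7 (chromosome 7, 43436391 to 43437339; 2.10, SE 0.22, 4.29-fold) and near the perforin gene Prf1 (3.03, SE 0.40).

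Of 24 type 1 and natural cytotoxicity receptor (NCR) genes with a peak, 14 had only higher peaks, 2 (Klrk1 and Stat4) only lower peaks, Cd226 both, and 7 none. Together 17 changed over all peaks and 21 adjusted over the list alone. The 14 included the type 1 cytokine Ifng, the granzyme gene Gzmb, the chemokine genes Ccl3, Ccl4, Ccl5 and Xcl1, and Tbx21 itself. The list's 102 peaks were higher as a set (median 0.38, camera adjusted p = 6.81e-05; adjusted p = 0.232 with an estimated correlation). Of 17 type 3 effector and receptor genes, 8 had only lower peaks, among them Ccl20, Csf2, Maf and Tnfsf11, 1 (Il18r1) only higher peaks and 3 both (12 changed over all peaks, 13 adjusted over the list alone). Their set test did not pass (median 0.01, mean -0.20, adjusted p = 0.523).

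Among 24 ILC transcription factor genes, 6 had only higher peaks, 3 only lower and 5 both (14 also adjusted over the list alone). Stat3 rose by 1.77 (SE 0.32), Bcl11b by 1.54 (SE 0.28) and a peak near Prdm1, which encodes Blimp-1 and also had a lower peak, by 1.25 (SE 0.21). Of 16 clock and REV-ERB/ROR response genes, 3 changed (also 3 adjusted over the list alone). A peak in Arntl, whose product BMAL1 drives the circadian clock, fell by 1.74 (SE 0.28, adjusted p = 0.000105), Bhlhe40 fell by 1.45 (SE 0.20), and Per3 rose by 1.17 (SE 0.20). Changed genes numbered 4 of 13 in the list of LTi-like ILC3 genes (LTi, lymphoid tissue inducer; 3 adjusted over the list alone) and 4 of 13 type 2 genes, where Arg1 fell by 1.62 (SE 0.32). They numbered 7 of 12 pan-ILC surface genes, 7 of 15 homing genes and 5 of 17 immediate early genes. By peak, 4 were higher and 4 lower of 62 in pan-ILC genes, and 5 and 5 of 70 in homing genes. Immediate early genes had 4 and 3 of 79, and LTi-like genes 2 and 2 of 73. Over all peaks, 12.3% changed. One gene changed among 8 MHC class II genes (Ciita) and 1 among 6 aryl hydrocarbon receptor (AHR) pathway genes (Tiparp). Adjusted over the list alone, these 6 lists from type 2 to AHR genes gave 4, 8, 8, 5, 1 and 1 changed genes. The set tests of the 9 lists in this paragraph had adjusted p of 0.511 or more.

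Markers of other cell types moved as well. Peaks at the B cell genes Blk, Ebf1 and Pax5 fell, Pax5 by 1.53 (SE 0.29), and the list of 4 genes with a peak was lower (median -0.44, adjusted p = 0.0294; adjusted p = 0.406 with an estimated correlation, and 0.0646 with peaks in the gene body and 5 kb around it). Of 6 T cell genes, Cd3e rose by 1.06 (SE 0.29) and Cd5 fell by 2.39 (SE 0.63). Myeloid genes changed in 1 of 6, epithelial genes in 3 of 7, stromal and endothelial genes in 2 of 5 (median 0.14, mean -0.03) and housekeeping genes in 1 of 12, with set adjusted p of 0.154 or more.

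In all, 4463 of 36251 peaks (12.3%) changed in limma, 1883 higher and 2580 lower, and 3356 of them by at least 2-fold. Higher peaks had 1319 nearest genes and lower peaks 1494. Only 9.19% of higher and 6.47% of lower peaks lay within 1 kb of a gene end, against 31.1% and 31.7% of the other peaks (Fisher's exact test, p = 3.69e-110 and 1.62e-204). Large increases included peaks in Zdhhc14 (3.83, SE 0.44) and Riok1 (3.54, SE 0.42), and large decreases one in Mlip (-4.08, SE 0.47). The peaks at Dynlt1b (chromosome 17, 6424651 to 6476947) ranked first among the increases. No fold is given for them because the controls held 1, 2 and 0 reads over the 6 peaks. RORgt-KO held 234 and 155 there, RORgt-Tbet-KO 387 and 540, and RORgt-RORa-KO 80, 0 and 255; Dynlt1b has near-identical copies, so these peaks are uncertain. The count fell to 1711 without RORgt-KO replicate 1 and to 2093 without replicate 2. With these 2 groups alone in the fit, 4541 peaks changed, 31.8% of them higher against 42.2%.

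**Figure D2:**
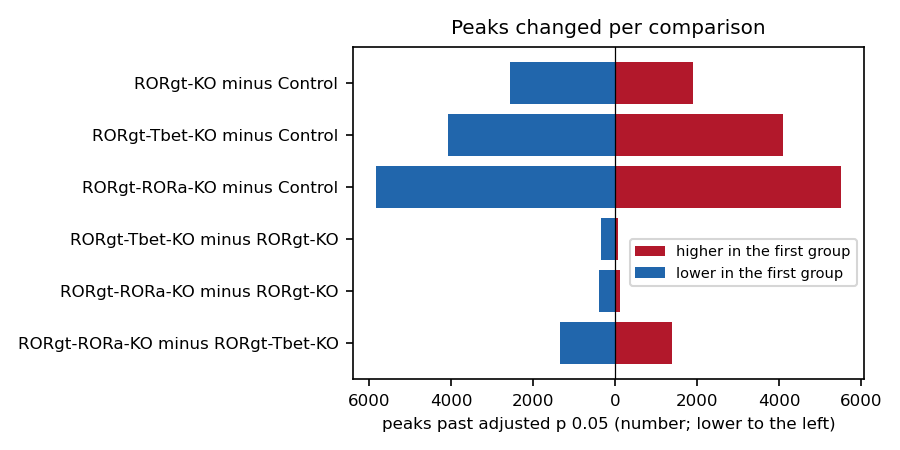
Number of peaks past an adjusted p of 0.05 (horizontal) in each of the 6 comparisons, higher in the first group to the right and lower to the left. Counts range from 415 between RORgt-Tbet-KO and RORgt-KO to 11326 between RORgt-RORa-KO and Control.

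RORgt-Tbet-KO was compared with the controls to see which regions change when both factors are lost. The Il17a peak at 20685830 fell by 3.76 (SE 0.45, 13.5-fold, adjusted p = 9.59e-07, n = 2 against 3), and a peak 13847 bp from Cd93 fell by 1.76 (SE 0.26). A peak at Il1r1, an interleukin-1 receptor gene with both higher and lower peaks, rose by 1.49 (SE 0.22, adjusted p = 1.43e-05). Peaks of LTi-associated genes rose, among them Cd83 (1.19, SE 0.20), the homing receptor Ccr7 (1.10, SE 0.23) and Il2ra (1.92, SE 0.37).

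Of 13 LTi-like ILC3 genes, 9 had only higher peaks, including Ccr6, Cxcr5, Cd4 and Ltb, 2 (Gpr183 and Sox4) only lower and Tnfsf11 both, so 12 changed, as also when adjusted over the list alone. The list was higher as a set (median 0.50, camera adjusted p = 0.000833; adjusted p = 0.392 with an estimated correlation). Pan-ILC surface genes followed, with 6 of 12 higher and 0 lower (6 also adjusted over the list alone; median 0.33, adjusted p = 0.00198; adjusted p = 0.392 with an estimated correlation). Itgb7, a subunit of gut-homing integrins, rose by 1.78 (SE 0.26). ILC transcription factor genes were higher too, with 10 of 24 only higher, 1 (Gata3) only lower and 8 both (19 changed, 20 adjusted over the list alone; adjusted p = 0.0436, and adjusted p = 0.392 with an estimated correlation). A peak in Zbtb16, which encodes PLZF and also had a lower peak, rose by 1.71 (SE 0.20, adjusted p = 7.48e-07). Depth was not separated from genotype for the LTi-like and pan-ILC sets, which were not retested at equal depth. The RORgt-Tbet-KO libraries held 4581343 and 5048636 reads. In RORgt-RORa-KO, the centred mean of LTi-like peaks was 0.106 in replicate 3 (4734879 reads) and -0.223 in replicate 2 (2272276 reads). Pan-ILC peaks gave 0.170 and -0.0444. In Control, LTi-like peaks were highest in replicate 3 (-0.0471), the library with fewest reads there.

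Immediate early genes, which cells induce within minutes of stimulation or handling, were higher in 11 of 17, including Fos (1.30, SE 0.25) and Nr4a1 (1.65, SE 0.24), and lower in 2, with Dusp1 down by 2.50 (SE 0.39). The count of changed genes was 13, and also 13 adjusted over the list alone. The set test gave an adjusted p of 0.000137 (adjusted p = 0.392 with an estimated correlation). Depth was not separated from genotype here either. In RORgt-RORa-KO, the centred mean of these peaks was 0.185 in replicate 3, the deepest, and -0.186 in replicate 2, the shallowest. In Control it was -0.114, -0.133 and -0.124. Type 1 and NCR genes were mixed: 11 had only higher peaks and 6 only lower, including Cxcr3, Ncr1 and Itga1 (-3.91, SE 0.61), with 17 changed in either adjustment and a set adjusted p of 0.106. Of 17 type 3 genes, 5 were only higher, 6 only lower and 4 both (15 in either adjustment; set adjusted p = 0.291). With only peaks in the gene body and 5 kb around it, this type 3 set was higher (adjusted p = 0.000909), tested at the preset correlation only. With all its peaks and an estimated correlation the adjusted p was 0.458. Peaks at Blk, Ebf1 and Pax5 fell again, Ebf1 by 2.56 (SE 0.60), Cd3e rose by 1.85 (SE 0.29) and Cd5 had both higher and lower peaks.

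Here 8189 peaks (22.6%) changed, 4093 higher and 4096 lower, 5256 of them by at least 2-fold. Large increases included peaks 2605 bp from Prdm14 (4.01, SE 0.35) and 8319 bp from Rpl11 (4.15, SE 0.40). Among higher peaks 16.3% lay within 1 kb of a gene end, against 31.7% of the others (Fisher's exact test, p = 1.12e-100). The count was 3359 without RORgt-Tbet-KO replicate 1, 3560 without replicate 2 and 12468 when libraries were weighted by their spread.

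RORgt-RORa-KO was compared with the controls to see the effect of losing both ROR factors. Peaks at type 3 cytokine genes closed. One 5891 bp from Il17a (chromosome 1, 20740387 to 20740965) fell by 3.23 (SE 0.22, 9.37-fold, adjusted p = 1.61e-11; 5.36 ± 0.55, SD, n = 3, against 8.59 ± 0.21, n = 3), one at Il17f fell by 3.24 (SE 0.24) and one 22832 bp from Tnfsf11, which encodes RANKL, fell by 2.82 (SE 0.42). Peaks at type 1 genes opened. Nkg7 rose by 2.78 (SE 0.19, 6.85-fold, adjusted p = 2.52e-11), a peak in Il12rb2 (67367869 to 67368223) by 4.71 (SE 0.47) and one near Xcl1 by 3.19 (SE 0.29).

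Of 24 type 1 and NCR genes, 16 had only higher peaks, 4 (Il12rb1, Itga1, Klrb1c and Klrk1) only lower, 2 both and 2 none, giving 22 changed in either adjustment, over all peaks or adjusted over the list alone. With 53 of 102 peaks higher and 9 lower, the set test gave an adjusted p of 7.06e-09 (median 0.73; adjusted p = 0.0579 with an estimated correlation). Of 17 type 3 genes, 7 had only lower peaks, 3 (Batf, Il18r1 and Lta) only higher and 5 both (15 in either adjustment; set adjusted p = 0.514). Of 24 ILC transcription factor genes, 23 changed in either adjustment, 12 only higher, 2 (Gata3 and Ikzf3) only lower and 9 both (set adjusted p = 0.199). By peak, 59 of 227 were higher and 34 lower, where 31.2% of all peaks changed. Tox and Bach2, both regulators of lymphocyte development, had peaks that fell by 2.95 (SE 0.36) and 3.05 (SE 0.40), and a peak near Prdm1 rose by 1.68 (SE 0.19); these 3 genes each had both higher and lower peaks.

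The Arntl peak at 113250772 fell by 2.33 (SE 0.25, adjusted p = 5.04e-08; the gene also had a higher peak), and 10 of 16 clock genes changed in either adjustment (3 only higher, 4 only lower; set adjusted p = 0.514). Among homing genes, a peak of the egress receptor gene S1pr1 fell by 1.46 (SE 0.16; the gene also had a higher peak), while the chemokine receptor gene Ccr2 rose by 2.71 (SE 0.48); 12 of 15 changed. LTi-like genes split, with 5 of 13 only higher, 4 only lower and 2 both (set adjusted p = 0.836). B cell markers were lower as a set (median -0.68, adjusted p = 0.0329; adjusted p = 0.469 with an estimated correlation, and 0.134 with peaks in the gene body and 5 kb around it). Of 6 T cell genes, 3 rose (Cd3d, Cd3e and Cd40lg, the last by 2.34, SE 0.38). Cd5 fell by 2.07 (SE 0.56) and Cd28 had both (5 changed in either adjustment). The T cell set did not pass in camera (median 0.60, adjusted p = 0.199, and 0.469 with an estimated correlation). It was higher in the fry test (adjusted p = 0.000684).

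Of all peaks 11326 (31.2%) changed, 5491 higher and 5835 lower, with 7384 changed by at least 2-fold. The share within 1 kb of a gene end was 11.6% of higher peaks, against 33.2% of the others (Fisher's exact test, p = 1.95e-262). Large decreases included peaks in Hibch (-4.44, SE 0.42) and 39653 bp from Rpia (-4.45, SE 0.46). Leaving out single libraries gave 9082 to 11851.

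**Figure D3:**
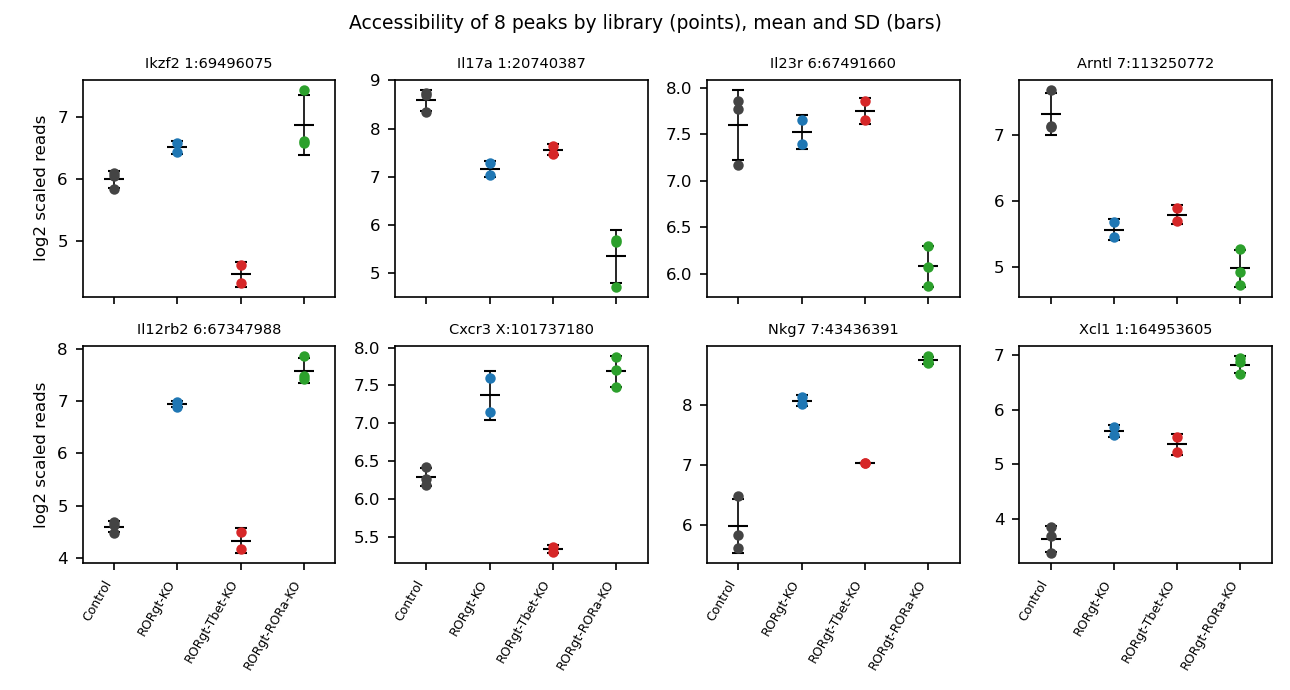
Log2 scaled read count (vertical) of 8 peaks, named by nearest gene, chromosome and start, in the 4 groups; coloured points are libraries, and bars give the mean and SD. This Il12rb2 peak, 1 of several in the gene, averaged 6.94 in RORgt-KO, 4.33 in RORgt-Tbet-KO and 7.59 in RORgt-RORa-KO.

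To isolate the effect of losing T-bet when RORgt was already absent, RORgt-Tbet-KO was compared with RORgt-KO. Peaks at some type 1 genes fell. The Il12rb2 peak at 67347988 fell by 2.61 (SE 0.30, 6.11-fold, adjusted p = 9.67e-06; 4.33 ± 0.24, SD, n = 2, against 6.94 ± 0.06, n = 2), one 3033 bp from Cxcr3, a chemokine receptor of type 1 cells, by 2.03 (SE 0.25, adjusted p = 1.8e-05), and one in Cd226 by 1.96 (SE 0.40). Other peaks in Il12rb2 stayed open without T-bet: the one at 67367150 was 6.36 ± 0.38 against 6.27 ± 0.37, and the one at 67367869 was 5.20 ± 0.05 against 5.13 ± 0.02. In all 8 of 24 type 1 and NCR genes had a lower peak and 0 a higher one, with 18 changed when adjusted over the list alone, at 22 lower and 8 higher peaks (median -0.03, mean -0.26, set adjusted p = 0.0278; adjusted p = 0.294 with an estimated correlation).

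Among ILC transcription factor genes, Ikzf2 (Helios) fell by 2.04 (SE 0.31), Ets1 by 1.92 (SE 0.31) and Bcl11b also fell, while Ikzf3 (Aiolos) rose by 1.38 (SE 0.24). The list of these factors was higher as a set (7 changed adjusted over the list alone; median 0.14, adjusted p = 0.0192; adjusted p = 0.248 with an estimated correlation). Of the type 3 genes, Cd93 and Il23r fell, the latter by 1.94 (SE 0.49), whereas the list as a set was higher (4 changed adjusted over the list alone; median 0.26, adjusted p = 0.00118; adjusted p = 0.248 with an estimated correlation). Other sets were higher with no gene past the test over all peaks or, except for immediate early genes and stromal genes, adjusted over the list alone. They were LTi-like, pan-ILC and immediate early genes (adjusted p = 1.15e-05 each; adjusted p = 0.248, 0.248 and 0.357 with an estimated correlation) and MHC class II genes (adjusted p = 0.0278; adjusted p = 0.357 with an estimated correlation, and 0.0583 with peaks in the gene body and 5 kb around it). With those peaks the clock set was higher (adjusted p = 0.026, against 0.0919) and the AHR set lower (adjusted p = 0.0297, against 0.0705), at the preset correlation only. With all their peaks and an estimated correlation the clock and AHR sets gave adjusted p = 0.377 and 0.357. Stromal and endothelial markers were also higher as a set (0 genes changed over all peaks and 1 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.248 with an estimated correlation). The 0 counts are from limma, in which 5 immediate early genes passed adjusted over the list alone. The RORgt-Tbet-KO libraries were deeper (4581343 and 5048636 reads) than the RORgt-KO libraries (3389482 and 2631420). These sets were not retested at equal depth.

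In this comparison 415 peaks (1.14%) changed, 65 higher and 350 lower. Large decreases included peaks 48532 bp from Hand2 (-4.75, SE 0.59, with few reads in RORgt-Tbet-KO) and 3277 bp from Coil (-4.03, SE 0.65), and a large increase was 20581 bp from Fam126a (2.92, SE 0.33). The count was 91 to 204 when single libraries were left out (91 without RORgt-KO replicate 1, 141 without its replicate 2, 124 without RORgt-Tbet-KO replicate 1, 204 without its replicate 2), 95 without the mean-variance trend, 3148 with library weights and 3341 with the 2 groups alone. The share of higher peaks was 15.7%, against 49.9% with library weights and 57.9% with the 2 groups alone.

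RORgt-RORa-KO was compared with RORgt-KO to isolate the effect of losing RORa. Peaks at some type 3 genes fell below their level in RORgt-KO, with the Il17a peak at 20740387 down by 1.80 (SE 0.25, 3.49-fold, adjusted p = 6.66e-05; 5.36 ± 0.55, SD, n = 3, against 7.16 ± 0.17, n = 2). Il17f fell by 1.48 (SE 0.24) and Il23r, the interleukin-23 receptor gene, by 1.44 (SE 0.23). The Il17a peak at 20685830 did not pass the test, at 3.85 ± 0.32 against 3.60 ± 0.20, and no peak of Il22 or Csf2 passed. Ccl20 and Cd93 fell too, so that 5 of 17 type 3 genes were lower and 0 higher (7 changed adjusted over the list alone; set adjusted p = 0.677). Type 1 and NCR genes were higher as a set (median 0.36, adjusted p = 1.51e-07; adjusted p = 0.0862 with an estimated correlation), although single genes passed only at Fasl, the Fas ligand gene (2.83-fold, adjusted p = 0.00151), and at Cd226, which fell by 1.07 (SE 0.27); 3 changed adjusted over the list alone. T cell markers shifted by a similar mean (0.37 for each list), with 0 genes changed over all peaks and 3 adjusted over the list alone (median 0.30, set adjusted p = 0.0758). Zbtb16 rose by 1.49 (SE 0.29), Egr2 by 1.60 (SE 0.24), and Tox, Tox2 and the clock gene Cry1 fell, Cry1 by 1.92 (SE 0.45).

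Peaks that changed numbered 534 (1.47%), 120 higher and 414 lower; outside the lists, a peak 1272 bp from Erich3 fell by 2.41 (SE 0.28, adjusted p = 9.45e-06). The count fell to 229 without RORgt-KO replicate 1 and to 86 without its replicate 2, to 45 without the trend, and rose to 1212 with library weights. With the 2 groups alone 390 passed, 43.8% of them higher against 22.5%.

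RORgt-RORa-KO and RORgt-Tbet-KO were compared directly to test whether the second deletion mattered. Peaks at type 1 genes were more open in RORgt-RORa-KO. The Il12rb2 peak at 67347988 was higher by 3.26 (SE 0.28, 9.57-fold, adjusted p = 1.9e-08), Cxcr3 by 2.35 (SE 0.23, 5.09-fold) and Nkg7 by 1.72 (SE 0.22, 3.31-fold), with n = 3 against 2. Peaks at type 3 genes were lower, the Il17a peak at 20740387 by 2.20 (-2.20, SE 0.25, adjusted p = 5.88e-07), Il17f by 1.88 (-1.88, SE 0.24) and the Il23r peak at 67491660 by 1.68 (-1.68, SE 0.23), while other Il23r peaks were higher.

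Of 24 type 1 and NCR genes, 16 were higher, among them Ifng, Ncr1 and Prf1, and 1 (Il12rb1) lower (17 in either adjustment; set adjusted p = 5.31e-09; adjusted p = 0.056 with an estimated correlation). Of 17 type 3 genes, 5 were only lower, Cd93 only higher and 3 both (9 changed, 10 adjusted over the list alone; adjusted p = 0.000715, and adjusted p = 0.158 with an estimated correlation). LTi-like genes were lower in 4 of 13, Ccr7, Cd83, Kit and Tnfsf11 (4 in either adjustment; adjusted p = 6.34e-05; adjusted p = 0.315 with an estimated correlation). Set tests were also lower for immediate early genes (7 of 17 lower, Egr2 higher by 1.80, SE 0.24; adjusted p = 0.000715), pan-ILC genes (2 of 12 lower, 1 higher; adjusted p = 0.0121) and clock genes (3 of 16 only lower, 1 only higher; adjusted p = 0.0121). With an estimated correlation these 3 gave adjusted p = 0.43, adjusted p = 0.43 and adjusted p = 0.315. Adjusted over the list alone, 9, 3 and 6 genes changed. Depth was not separated from genotype for the LTi-like, immediate early and pan-ILC sets. Type 2 genes rose at Gata3, Klrg1, Il1rl2 and Il1rl1, the interleukin-33 receptor gene (2.08, SE 0.38; set adjusted p = 0.488). Ikzf2 and Ets1 were higher by 2.40 (SE 0.28) and 2.29 (SE 0.29). Of other cell types' markers, Cd40lg was higher by 2.67 (SE 0.43), Itgam was higher by 1.83 (SE 0.42) and Krt8 was lower (-2.23, SE 0.25).

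The direct comparison called 2733 peaks (7.54%), 1383 higher and 1350 lower, 6.80% and 9.70% of them within 1 kb of a gene end. A peak 48532 bp from Hand2, with few reads in RORgt-Tbet-KO, was higher by 5.50 (SE 0.54). The count was 967 without RORgt-Tbet-KO replicate 1, 1032 without its replicate 2, 1505 without the trend and 6272 with library weights.

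The 3 comparisons with the controls shared much of their change. Log2 fold changes of RORgt-KO and RORgt-RORa-KO correlated at 0.857 across peaks, which are not independent replicates, against 0.449 simulated for unchanged groups set against the same controls. The covariance was 0.629 against 0.0713 simulated. They shared 1747 higher and 2307 lower peaks, where independent lists would share 285 and 415. RORgt-KO and RORgt-Tbet-KO correlated at 0.798 (simulated 0.420; covariance 0.551 against 0.0713) and shared 1352 higher and 1950 lower peaks (213 and 292 for independent lists). RORgt-Tbet-KO and RORgt-RORa-KO correlated at 0.765 (simulated 0.470; covariance 0.660 against 0.0712), sharing 2696 and 2930 (620 and 659). Simulated overlaps averaged 0.05 peaks or fewer, but no peak was changed in these simulations, so hardly any could be called. They do not measure the overlap that shared controls give when many peaks are called. Part of the excess over independent lists may come from the shared controls, whose 3 libraries cannot be divided into groups of 2. One pair of comparisons shared no library, RORgt-RORa-KO against Control and RORgt-Tbet-KO against RORgt-KO. Their fold changes correlated at 0.0592, yet 209 peaks were higher in the first and lower in the second, where independent lists would share 53.0 (Fisher's exact test, p = 4.46e-82). These 209 were 59.7% of the 350 peaks lower without T-bet, and they were among 5491 peaks higher in the first. Peaks higher in both numbered 29, where independent lists would share 10 (Fisher's exact test, p = 1.4e-08), of 65 peaks higher without T-bet. Peaks lower in both numbered 24, where independent lists would share 56.3 (odds ratio 0.381, Fisher's exact test, p = 3.47e-07).

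**Figure D4:**
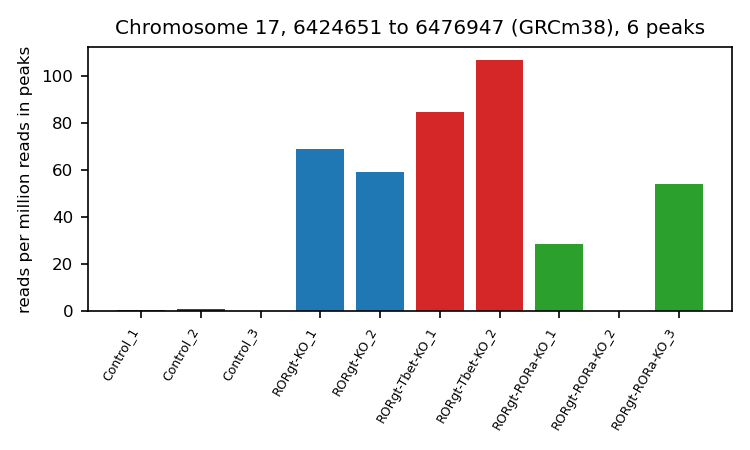
Reads scaled to the depth of each library (vertical, as on the axis) over the 6 peaks at Dynlt1b, one bar per library coloured by group. Control libraries lie at 0.595 or below, RORgt-RORa-KO replicate 2 at 0, and the other knockout libraries between 28.3 and 107.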

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

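Most tests in this part were chosen only after the results were seen; thinning of the libraries, the other scalings of the type 1 list and the splits of libraries were written down before. The effects of the RORgt-Tbet-KO and RORgt-RORa-KO deletions against the same controls differed at 2733 peaks in limma's direct contrast of the groups. Among them, the contrast was 3.26 (SE 0.28) at Il12rb2, -2.20 (SE 0.25) at Il17a and 5.50 (SE 0.54) near Hand2.

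Of 24 type 1 and NCR genes, 14 had only higher peaks in RORgt-KO, and, adjusted over all peaks, 8 had a lower peak and 16 no called peak in RORgt-Tbet-KO against RORgt-KO (18 changed adjusted over the list alone). The list's camera adjusted p in RORgt-KO against Control was at most 0.000142 under 3 other scalings (adjusted p = 0.232 with an estimated correlation). That test sets list peaks against all other peaks, so a shift common to a library's peaks largely cancels. The scalings therefore decide little about scaling as a cause. A sort with fewer LTi-like cells might raise type 1 signal, but the median change of LTi-like genes was 0.0879 where such a loss predicts a value below 0; no cell counts were used here, so this is not settled. A gain that depends on T-bet predicts that peaks opened in RORgt-RORa-KO are lower when Tbx21 is deleted from RORgt-KO. Of 5491 opened peaks, 209 were lower (53.0 for independent lists, odds ratio 8.59, Fisher's exact test, p = 4.46e-82). Another 29 were higher in RORgt-Tbet-KO than in RORgt-KO (10 for independent lists, odds ratio 4.53, Fisher's exact test, p = 1.4e-08). Most opened peaks passed in neither direction. Peaks that closed in RORgt-RORa-KO were under-represented among those lower without T-bet (24, 56.3 for independent lists, odds ratio 0.381, Fisher's exact test, p = 3.47e-07). Opened peaks were thus over-represented among peaks that changed either way without T-bet, and whether the gain depends on T-bet is left open. The contrasts share 1 estimate of spread per peak, so their lists of calls are not fully independent.

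The 6 neighbouring peaks at Dynlt1b held 1, 2 and 0 reads in the controls and many in most knockouts. Regulation by the deleted genes predicts reads in every RORgt-RORa-KO library, 64.3 in replicate 2 at the lowest rate of its group. That library held 0, as a copy-number or sequence variant that segregates among the mice could give. The observation rests on 1 library and no genotype was used here, so regulation is not excluded.

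Control replicate 3 lay nearer the knockouts on the first component than the other controls. Its lower depth is an unlikely cause, because with all libraries thinned to 1 depth the gap to the nearest control was 107% of the gap before. Sex may matter. In the knockout groups, libraries with reads on Y outside the pseudoautosomal region lay at most 11.6 higher than those without. In the controls the shift was 47.5, which is that of replicate 3 itself, the only control with such reads. Libraries could pool mice of both sexes, so the shifts in the knockout groups do not settle this. Admixed knockout cells carrying the Dynlt1b segment would give 46.3 reads there at the share of 27.5% read from the component, and 0 were seen; knockout cells without the segment are not excluded. The cause is left open.

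Of 10 splits of the 6 Control and RORgt-RORa-KO libraries into groups of 3, 1 (the real one) called 9744 peaks with these groups alone and the highest other called 0; 10 splits are too few for a share under 0.05.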

How the results depend on the processing

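The tests with voom, a covariate for reads on Y outside the pseudoautosomal region and length corrections were chosen only after the data were seen, as were the replicate block and the left-out libraries for the F test; the others were planned. No named peak reversed. Of the named peaks called, 24 of 52, 44 of 61, 58 of 64, 5 of 23, 0 of 23 and 20 of 46 stayed past the threshold in every setting, in the order RORgt-KO, RORgt-Tbet-KO and RORgt-RORa-KO against Control, RORgt-Tbet-KO and RORgt-RORa-KO against RORgt-KO, and RORgt-RORa-KO against RORgt-Tbet-KO. The 0 of 23 was fixed by 1 setting, length correction with the replicate block, which called 0 peaks in that contrast. Of these 23 peaks, 18 were lost when a library was left out, 6 with voom and 0 with the replicate block alone. Leaving out 1 library gave 1711 to 5092, 3359 to 8918, 9082 to 11851, 91 to 204, 86 to 606 and 967 to 3778 peaks in the order above; a group left with 1 library is assumed to vary like the others. Without Control replicate 3 the first 3 counts were 5092, 8918 and 11851. Library weights (0.44 to 1.97) gave 12468 for RORgt-Tbet-KO against Control, 3148 and 1212 against RORgt-KO, and 6272 for RORgt-RORa-KO against RORgt-Tbet-KO; the weights favour the 2 RORgt-Tbet-KO libraries. Without the trend the last 3 contrasts gave 95, 45 and 1505. A fold of at least 2 left 5256 and 7384 for RORgt-Tbet-KO and RORgt-RORa-KO against Control, by construction. For RORgt-Tbet-KO against RORgt-KO, voom gave 664, the Y covariate 704 and the 2 groups alone 3341; the share of higher peaks was 15.7% in the report, 29.1%, 31.7% and 57.9% there, and the cause was not tested. Deviations of same-numbered libraries from their group means correlated at r = -0.121 to 0.143 over 13 pairs. In groups of 2 the deviations mirror each other, so these pairs are not independent. Pairing by replicate number is not excluded, because a replicate block called more peaks in every contrast. A replicate block gave 5659, 10130, 11985, 666, 605 and 3490; with it the B cell list in RORgt-KO against Control had an adjusted p of 0.0505 and the T cell list in RORgt-RORa-KO against RORgt-KO 0.0479. Length correction gave 156, 112 and 1688 for the last 3 contrasts and, with the replicate block, 64, 0 and 1562; the 0 stood beside 4441 peaks at unadjusted p < 0.05. With the trend fitted on uncorrected means the length correction gave 428, 461 and 2608, so the drop without the replicate block came from the trend's covariate. The cause of the drop with the block was not tested. Other scalings moved the share of higher peaks by under 10 points and ended 3 list calls: B cell in RORgt-KO against Control (0.0535, loess), clock in RORgt-RORa-KO against RORgt-Tbet-KO (0.0518, quantile) and ILC transcription factors in RORgt-Tbet-KO against Control (0.0523, median centring). With list peaks limited to the gene body and 5 kb around it, 3 list calls were lost and 3 gained, all in the same direction: B cell in RORgt-KO (0.0646) and RORgt-RORa-KO (0.134) against Control and MHC class II in RORgt-Tbet-KO against RORgt-KO (0.0583) were lost; type 3 in RORgt-Tbet-KO against Control (0.000909), and clock (0.026) and AHR (0.0297) in RORgt-Tbet-KO against RORgt-KO, were gained. These narrower lists were tested at the preset correlation only. The fry test of each list alone lost 10 and gained 11. GC correction and motif association were not run. The F test stayed between 7843 and 15618. The median peak held 37 to 73 reads per library. With 200 peaks changed in the simulation, 2-fold changes were recovered in under 50%. The adjusted threshold is stricter when few peaks change. Recovery in contrasts with many more calls may therefore be higher and was not measured.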

Other observations

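The tests for genes with many changed peaks were chosen only after the data were seen. Among 1671 genes with at least 5 peaks, a hypergeometric test asked whether a gene held more changed peaks than its share. It treats neighbouring peaks as independent draws, which they need not be, so its p values may be too small. In RORgt-KO against Control, 5 genes passed for higher peaks, of which Dynlt1b, whose peaks are uncertain, ranked first (6 of 6, adjusted p = 3.22e-05). The others included the interleukin-21 receptor gene Il21r (4 of 5 peaks, adjusted p = 0.0115) and Il12rb2 (5 of 5). For lower peaks 7 passed, including Il17a (4 of 5, adjusted p = 0.0236) and Mitf, a melanocyte and mast cell factor (4 of 5). RORgt-Tbet-KO against Control gave 36 higher genes, among them the adaptor gene Grap2 (8 of 9 peaks, adjusted p = 0.00044), Runx3 (8 of 13) and the interferon receptor gene Ifnar1 (6 of 8), and 27 lower genes. RORgt-RORa-KO against Control gave 18 higher genes, including Dapk2 (8 of 10), Tgfbr2, a receptor for TGF-beta (8 of 12), and Fasl (7 of 9), and 18 lower genes, including Plxna2 (8 of 8) and Ednrb (7 of 8).

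Reads in peaks on Y outside the pseudoautosomal region were 0 in Control replicates 1 and 2, RORgt-KO replicate 2, RORgt-Tbet-KO replicate 1 and RORgt-RORa-KO replicate 2. They were 222 in Control replicate 3, 260 in RORgt-KO replicate 1, 390 in RORgt-Tbet-KO replicate 2, and 187 and 183 in RORgt-RORa-KO replicates 1 and 3. At 3 peaks near Pls3 (chromosome X, 75733660 to 75744805), reads were 285, 298 and 12 in Control, 3 and 205 in RORgt-KO, 266 and 4 in RORgt-Tbet-KO, and 56, 136 and 167 in RORgt-RORa-KO. The counts of 12, 3 and 4 were in libraries with reads on Y, and libraries without such reads held 136 or more. RORgt-RORa-KO replicates 1 and 3, with reads on Y, held 56 and 167. The low counts thus followed reads on Y within Control, RORgt-KO and RORgt-Tbet-KO. In RORgt-RORa-KO the raw counts did not follow them. Replicate 2, without reads on Y, held 136 at 2272276 reads in peaks, and replicate 3 held 167 at 4734879. Whether genotype also matters at these peaks is left open.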
